A study of Mus musculus with 15 samples.

How the data were processed

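Forebrain RNA of mice was measured on 15 Affymetrix Mouse Genome 430 2.0 arrays, which carry short oligonucleotide probes combined into probe sets. Per the labels, the samples were total RNA of mouse forebrain and fell into 3 groups of 5 arrays: vehicle with sham surgery (VEH-Sham 1 to 5), vehicle with hypoxic ischemia (VEH-HI 6 to 10) and erythropoietin with hypoxic ischemia (EPO-HI 11 to 15). Erythropoietin was given into the peritoneum at 5 U per g, and each injection came 1 h before the procedure, per the labels. Age, sex, the time between injury and sampling and the processing batch are not given in the sources used here. Replicate numbers run through the whole series, so no numbers pair arrays of different groups. The labels do not say that the samples are separate animals. The limma and permutation p-values therefore measure the spread between these samples, which may be technical.

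The deposited values are linear intensities, 1 per probe set and array, as the authors' software summarised them. The summary software is not given in the sources used here. From the values, the authors scaled each array so that its mean intensity, with 2% of probe sets trimmed at each end, is 150.0. All 15 value columns were matched to a sample by name, and 0 were left unmatched. The table holds 45101 probe sets, of which 64 are control probe sets and were left out of all tests.

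Gene names came from a probe annotation table of the platform and were updated by gene number against the mouse gene table of assembly GRCm38.p6, used for names only. Of the 45037 probe sets without controls, 34945 had 1 gene symbol, 932 had several and 9160 were not listed. The update matched 34741 by gene number and changed 0 symbols. Probe sets with several symbols or none were counted and not named.

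The rules for scaling, filtering, testing, naming genes and the 28 gene lists were fixed before the data were examined. Intensities were converted to log2(intensity + 16) and used as deposited, because the trimmed means were equal. Fold changes are on this scale and understate the changes of dim genes. The 60% of probe sets with the highest mean over all arrays were tested, which left 27022 (mean log2 of at least 5.46). All 15 arrays entered 1 linear model with 3 group means in limma 3.58.1 (lmFit, then eBayes with trend) under R 4.3.3. Tests were two-sided, and adjusted p-values are Benjamini-Hochberg values over all tested probe sets with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

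For statements on genes, each gene was represented by its brightest tested probe set with 1 symbol (13168 genes). The naming rule took the 10 largest rises and 10 largest falls past the threshold for VEH-HI against VEH-Sham and for EPO-HI against VEH-HI. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named as not passing. For EPO-HI against VEH-Sham the rule took 5 rises and 5 falls. Of each list, up to 4 members with the smallest p after hypoxic ischemia and up to 2 with the smallest p after erythropoietin could be named, and Epo and Epor were always to be named. Predicted genes without a proper name were counted only.

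The lists covered immediate early genes, heat shock and chaperones, hypoxia-inducible genes, the unfolded protein and integrated stress response, NRF2 targets and metallothioneins, glucocorticoid-responsive genes, cytokines with chemokines and adhesion molecules, interferon response and MHC class I, erythropoietin receptor signalling, apoptosis, cell cycle, sterol synthesis, and growth factors with neurotrophic genes. Others held markers of microglia and macrophages, neutrophils, reactive astrocytes, astrocytes, neurons, striatal projection neurons, hypothalamus and pituitary, thalamus, cerebellum, choroid plexus, meninges and fibroblasts, oligodendrocytes and myelin, oligodendrocyte precursors, endothelium and blood-brain barrier, and erythroid cells and blood. Of 519 listed members 429 were tested, and 3 of 516 distinct genes (Cdkn1a, Osm and Socs3) stood in more than 1 list. Mouse forebrain expresses many of the listed genes itself, so no list marks a foreign tissue by its presence alone. Lists were tested with camera at its preset correlation of 0.01, adjusted over the 28 lists of a comparison. This preset treats the genes of a list as nearly independent. The correlation estimated from the residuals was 0.56 for sterol synthesis, 0.41 for cytokines, 0.36 for reactive astrocyte genes and 0.32 for microglia and macrophages. For such lists the preset p-values can be far too small, since they largely reflect the number of genes. Camera with an estimated correlation, fry, and an exact two-sided permutation of the mean list score per array (252 splits, smallest possible p 0.00794) were run beside the preset.

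The arrays differed in a way the labels do not record. Divided at the largest gap between array medians (0.240 on the log2 scale), 4 arrays formed set A and 11 formed set B. Set A held VEH-Sham 1 to 4. Set B held VEH-Sham 5 and all 10 arrays of both hypoxic ischemia groups. With the array set as a block, the effect of hypoxic ischemia rests on VEH-HI minus VEH-Sham 5, so blocked and within-set values are the same number and depend on 1 sham array. Set A gives no value of its own because it holds 1 group.

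Alternatives fixed before the data were examined were quantile normalization, equal array medians, pseudocounts of 1 and 64, no filter, the upper 40% of probe sets, only the 2 groups compared, eBayes without trend, array weights, leaving out each array in turn, an estimated correlation, fry, the mean of all probe sets of a gene, and, for the correlation of effects, split VEH-HI arrays and called probe sets only. The array set as a block, the mixed set alone, the block with quantile normalization and the permutation of list scores were chosen after seeing the data.

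The procedure was tested on simulated data for EPO-HI against VEH-HI, with 200 of 27022 probe sets changed in each of 10 draws. It called 36.7% of probe sets changed by 0.5 on the log2 scale, 89.4% of those changed by 1 and 99.5% of those changed by 2, and 4.93% of its calls were false. The simulated spread came from the fit with the array set as a block, and no array-set difference was added. The real arrays were tested without that block, so these shares may be too high for them. A list of 20 genes moved by 0.3 had a camera p under 0.05, not adjusted over lists, in 10 of 10 draws, and an unmoved list in 0. The simulated genes varied independently, whereas the correlation estimated for the sterol synthesis list was 0.56. These draws therefore do not show how often camera calls unmoved lists of correlated genes. Arrays give no read depth, and the number of arrays limits the precision.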

Results

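The series asks how erythropoietin, the hormone that drives red blood cell formation and is studied as a neuroprotective agent, affects gene expression in the mouse forebrain after hypoxic ischemia, a combined shortage of oxygen and blood flow. Expression was measured in 5 VEH-Sham, 5 VEH-HI and 5 EPO-HI samples, with no group that received erythropoietin and sham surgery. Values are log2(intensity + 16), and changes are given as log2 differences with their standard error (SE, n = 5 per group).

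The 15 arrays formed 2 sets that crossed the groups only through VEH-Sham 5. Median intensities were 55.3 to 57.9 in VEH-Sham 1 to 4 (set A) and 39.2 to 44.4 in VEH-Sham 5 and the 10 hypoxic ischemia arrays (set B). Over the tested probe sets, arrays correlated at 0.968 to 0.972 within set A, 0.962 to 0.982 within set B and 0.927 to 0.954 between the sets. The first principal component held 39.7% of the variance, with scores of -56.9 to -49.7 in set A, 11.9 to 25.3 in the hypoxic ischemia arrays and 13.2 in VEH-Sham 5. The ratio of 3' to 5' Gapdh control signal, a sign of RNA quality, was 0.634 to 0.719 in set A and 0.716 to 0.756 in set B, and that of Actb 1.283 to 1.399 and 1.241 to 1.504. Values against VEH-Sham are therefore given with the value within set B, which is the difference from VEH-Sham 5 alone.

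**Figure D1:**
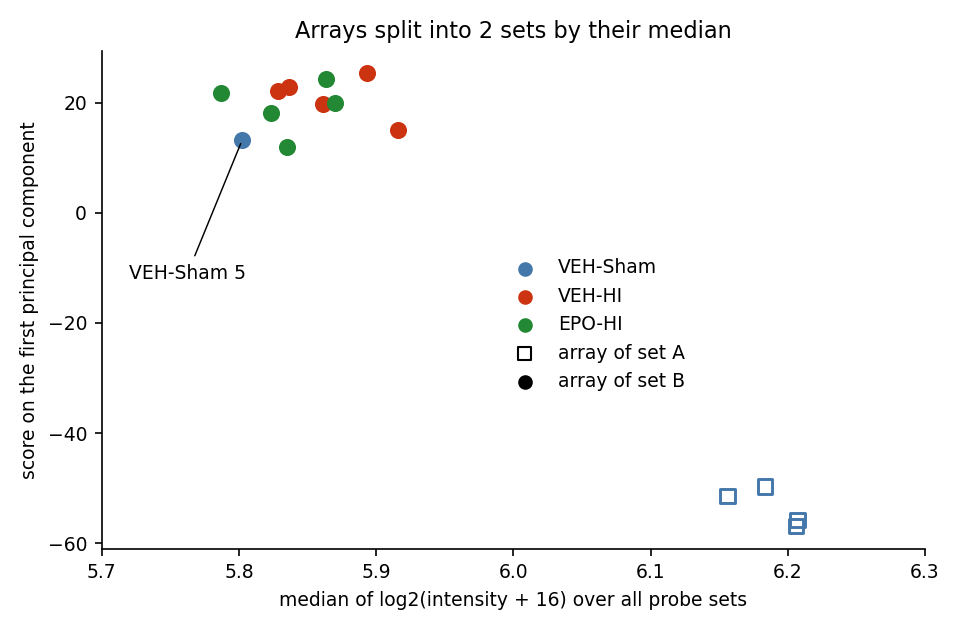
Median of log2(intensity + 16) over all probe sets (horizontal axis) against the score on the first principal component (vertical axis, log2 units) for each of the 15 arrays, coloured by group. VEH-Sham 1 to 4 (open squares, set A) have medians of 6.16 to 6.21, and all other arrays (filled circles, set B), VEH-Sham 5 among them, lie at 5.79 to 5.92.

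The comparison of VEH-HI with VEH-Sham asks what hypoxic ischemia changes when no erythropoietin is given. Genes of inflammation and of glial reaction were among the 10 largest rises. Ccl12, a chemokine that attracts monocytes, went from 4.53 ± 0.10 to 8.01 ± 0.97 (SD, n = 5 each), an 11.2-fold rise (3.48, SE 0.38, limma adjusted p = 2.96e-05) that was 3.55 within set B. Lgals3, which encodes the carbohydrate-binding protein galectin-3 of activated microglia and macrophages, rose by 2.48 (SE 0.28, limma adjusted p = 3.1e-05, 1.85 within set B). Serpina3n, a protease inhibitor of reactive astrocytes, rose by 2.40 (SE 0.39, limma adjusted p = 0.00075, 1.23 within set B).

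The other large rises included the macrophage gene Mpeg1 (2.14, SE 0.24, limma adjusted p = 2.96e-05), the chemokine gene Ccl3 (2.22, SE 0.34, 0.000487), the lipopolysaccharide co-receptor gene Cd14 (2.03, SE 0.33, 0.000822) and Socs3, a feedback inhibitor of cytokine signalling (1.97, SE 0.40, 0.00294). Within set B these were 1.11, 1.86, 2.18 and 1.99. Pdlim4, an actin-associated gene, rose by 2.08 (SE 0.27, limma adjusted p = 0.000144) and by 0.96 within set B. S100a9, a calcium-binding protein of neutrophils, rose by 2.45 (SE 0.68, limma adjusted p = 0.0152) with a within-set value of 1.74, and VEH-Sham 5 lay inside the range of the VEH-HI arrays. Clec16a, a regulator of autophagy, passed at 1.99 (SE 0.34, limma adjusted p = 0.00114), but the difference from VEH-Sham 5 was -0.06.

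The 10 named falls were all smaller within set B or, for Igdcc3 and Bcas2, above 0. They were -1.77 for the secreted-protein gene Bpifb1 (SE 0.32, limma adjusted p = 0.00151), -1.72 for the immunoglobulin heavy chain gene Ighg3, -1.72 for the transcription factor gene Casz1, -1.68 for Igdcc3 and -1.60 for the ubiquitin ligase gene Marchf10. Within set B these genes were at -0.53, -0.05, -0.34, 0.01 and -0.73. Bcas2, a splicing factor gene, was at -1.57 (0.17 within set B, and 0 of 1 other probe sets went the same way), Tmem266 at -1.56 (-0.71), the centrosomal gene Pcnt at -1.41 (-0.50) and Tmem125 at -1.40 (-0.87). Zfp991 was at -1.40 (-1.22 within set B, limma adjusted p = 0.0426), and 1 of 2 other probe sets went the same way. Its call was lost without any 1 of VEH-Sham 1 to 4 and VEH-HI 6, 7 and 9 (adjusted p 0.0521 to 0.126) and its adjusted p ranged from 0.0116 to 0.126 over all settings that ignore the array set.

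In all, 6174 of 27022 probe sets passed (limma, Benjamini-Hochberg), 2661 higher (43.1%) and 3513 lower. They represented 1573 genes with a higher and 1510 with a lower level, and 901 of the probe sets had no single symbol. With the array set as a block 3 probe sets passed, all higher and named here after their values were seen: 1449254_at (unnamed here, 3.99), 1442622_at (unnamed here, 1.67) and Mnt (1.59). Within set B 7 passed. Of the 2661 higher calls 86.0% kept their direction within set B, with a median of 0.48 reduced to 0.19, and of the lower calls 81.0%, with a median of -0.61 reduced to -0.20. These shares are raised by selection, since the calls were made with the same VEH-HI arrays and VEH-Sham 5. Over the 9539 probe sets called between EPO-HI and VEH-Sham 1 to 4, which share no array with VEH-HI minus VEH-Sham 5, 57.0% had the same direction in the latter, against 45.9% to 62.3% with each VEH-HI array in the place of VEH-Sham 5. The count fell to 4081, 3890 and 3824 without VEH-Sham 1, 3 and 4, and was 9609 without VEH-Sham 5. Quantile normalization called 5720 (53.3% higher) and equal array medians 7727 (85.6% higher), the latter moving the median change of all probe sets from -0.06 to 0.18.

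Reactive astrocyte genes, cytokines with chemokines and adhesion molecules, and microglia and macrophage markers rose together. Of 21 reactive astrocyte genes 12 rose and 0 fell, 9 did not pass, and adjusted over the list alone 12 rose and 1 fell (median 1.11, 1.15 within set B, camera adjusted p = 1.13e-07). Examples were Vim, an intermediate filament gene (1.23, SE 0.14), Timp1, an inhibitor of matrix proteases (1.72, SE 0.20), and the sphingosine 1-phosphate receptor gene S1pr3 (1.56, SE 0.28), at 1.27, 1.75 and 1.59 within set B. Of 20 cytokine, chemokine and adhesion genes 14 rose and 6 did not pass, and 14 rose adjusted over the list alone (median 0.90, 1.00 within set B, camera adjusted p = 4.98e-07). Csf1, a growth factor for microglia and macrophages, rose by 0.90 (SE 0.17, 0.90 within set B), although 0 of its 3 other probe sets went the same way. Of 22 microglia and macrophage markers 14 rose, 1 fell and 7 did not pass, and 16 rose and 1 fell adjusted over the list alone (median 0.51, 0.73 within set B, camera adjusted p = 3.95e-07). C1qc, a complement gene (1.33, SE 0.16), Tyrobp, a microglial signalling adaptor gene (1.13, SE 0.15), and the lysosomal gene Cd68 (1.08, SE 0.16) were at 1.17, 0.93 and 1.39 within set B. Each of the 3 lists had an adjusted p = 0.326 with an estimated correlation and 0.037 by exact permutation of its scores. With the array set as a block their camera adjusted p-values were 6.2e-13, 2.55e-12 and 3.95e-13, but 0.151 each with the block and an estimated correlation.

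Sterol synthesis genes fell. Of 16 measured members 14 fell, 0 rose and 2 did not pass, and 15 fell adjusted over the list alone (median -0.47, -0.73 within set B, camera adjusted p = 8.4e-08, 7.87e-22 with the block). The list had an adjusted p = 0.326 with an estimated correlation, 0.151 with that and the block, and 0.037 by exact permutation. Cyp51, a sterol demethylase gene, was at -0.60 (SE 0.09), Nsdhl at -0.69 (SE 0.11), the isoprenoid synthesis gene Fdps at -0.73 (SE 0.15) and the cholesterol transfer gene Stard4 at -0.79 (SE 0.15). Within set B they were at -0.66, -1.03, -0.94 and -0.83.

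A further 4 lists passed in all arrays but not with the array set as a block. NRF2 targets and metallothioneins rose, with 6 of 13 higher and 0 lower, and 7 higher and 1 lower adjusted over the list alone (median 0.28, 0.02 within set B, camera adjusted p = 0.00452, 0.0668 with the block). The metal-binding Mt1 and Mt2 rose by 1.84 (SE 0.24) and 1.75 (SE 0.23), at 1.26 and 1.39 within set B, and the heme-degrading Hmox1 by 1.52 (SE 0.32, 0.89 within set B). Of 15 astrocyte markers 5 rose and 0 fell, 8 and 0 adjusted over the list alone (median 0.30, 0.09 within set B, camera adjusted p = 0.00219, 0.248 with the block), with the folate enzyme gene Aldh1l1 at 0.83 and 0.40 and Mlc1 at 0.51 and 0.14. Of 11 meningeal and fibroblast markers 5 rose and 0 fell, 6 and 0 adjusted over the list alone (median 0.37, 0.02 within set B, camera adjusted p = 0.00143, 0.289 with the block), with the collagen gene Col3a1 at 0.79 and 0.53 and the retinoic acid synthesis gene Aldh1a2 at 0.92 and 0.64. Of 12 striatal projection neuron markers 5 fell and 0 rose, also adjusted over the list alone (median -0.28, -0.18 within set B, camera adjusted p = 0.00221, 0.147 with the block), with the phosphodiesterase gene Pde10a at -0.97 and -0.37 and Ppp1r1b, a phosphatase inhibitor gene, at -0.65 and -0.30. For these 4 lists the camera adjusted p was 0.326, 0.415, 0.326 and 0.326 with an estimated correlation. No list passed with an estimated correlation, while fry called 8 lists and exact permutation 6. Without VEH-HI 10 camera called 13 lists, and with no filter on dim probe sets 14.

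**Figure D2:**
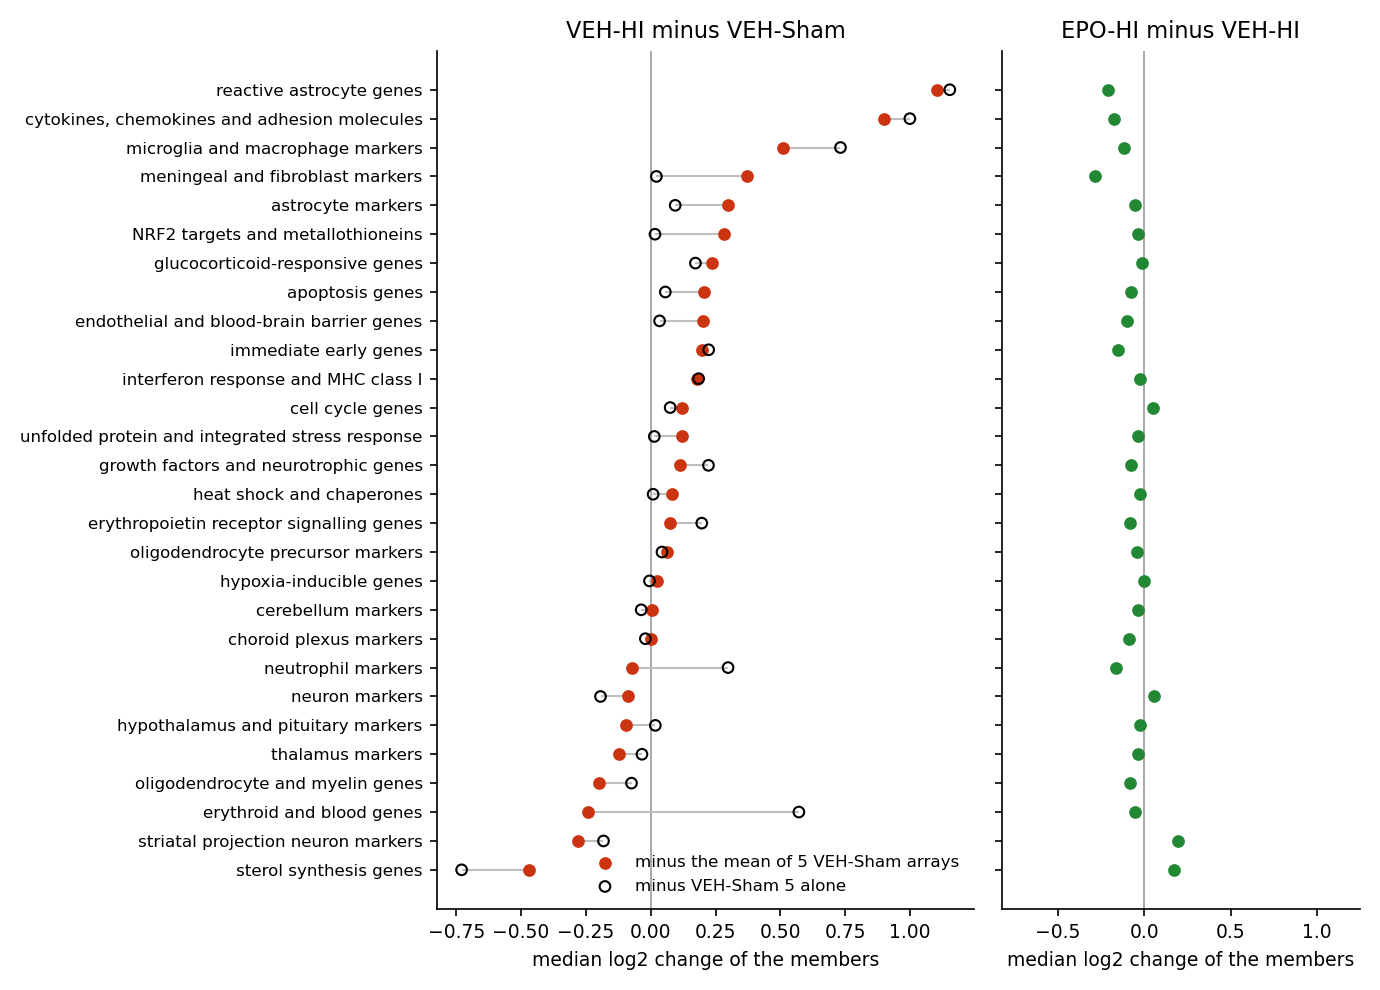
Median log2 change of the tested members of each of the 28 gene lists (horizontal axes) for VEH-HI minus VEH-Sham (left) and EPO-HI minus VEH-HI (right). Filled points use all 5 VEH-Sham arrays and open circles VEH-Sham 5 alone. Reactive astrocyte genes lie at 1.11 and 1.15, whereas NRF2 targets lie at 0.28 and 0.02.

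The stress and signalling lists did not pass as groups, although members did (counts adjusted over the list alone in brackets). Over all 13168 tested genes 1573 were called higher and 1510 lower. The heat shock, cell cycle and growth factor counts below lie near or under that share, so they show no response of these lists. Of 24 immediate early genes 7 rose and 1 fell (10 and 3 adjusted over the list alone), among them the transcription factor genes Fos at 1.80 (SE 0.43), Atf3 at 1.15 (SE 0.30) and Egr3 at -0.79 (SE 0.13), which were 1.48, 1.34 and -0.43 within set B. The other probe set of Egr3 did not share its direction. Of 25 hypoxia-inducible genes 5 rose and 2 fell (6 and 2), with the lipid droplet gene Plin2 at 1.47 (SE 0.24, 1.502 within set B) and the angiogenic factor gene Vegfa at -0.85 (SE 0.12, -0.58 within set B), whose other probe set did not share its direction. Of 22 apoptosis genes 7 rose and 3 fell (8 and 3), with the pro-apoptotic Bbc3 at 0.55 (0.55 within set B) and Casp9 at -0.66 (-0.43). Rises and falls numbered 3 and 2 of 20 heat shock and chaperone genes (5 and 2), 5 and 1 of 22 unfolded protein and integrated stress response genes (5 and 1), 4 and 0 of 12 glucocorticoid-responsive genes (5 and 0) and 5 and 1 of 18 interferon response and MHC class I genes (6 and 1). They numbered 2 and 0 of 18 cell cycle genes (2 and 0), with the replication genes Mcm5 at 0.86 and Pcna at 0.48 (0.49 and 0.22 within set B), and 1 and 0 of 12 growth factor and neurotrophic genes (1 and 0). In the order named, the medians of these 9 lists were 0.20, 0.02, 0.20, 0.08, 0.12, 0.24, 0.18, 0.12 and 0.11, and within set B they were 0.22, -0.00, 0.06, 0.01, 0.01, 0.17, 0.18, 0.08 and 0.22. The smallest camera adjusted p was 0.0503, for interferon response and MHC class I.

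The counts of marker genes below stand beside 1573 higher and 1510 lower calls over all 13168 tested genes. Among marker lists of other cells and regions, 2 of 28 neuron markers rose and 4 fell, near that share, also adjusted over the list alone (median -0.09, camera adjusted p = 0.366). Within set B their median was -0.19 and the list passed with the block (camera adjusted p = 6.82e-05, but 0.151 with an estimated correlation). Of 8 neutrophil markers 2 rose and 0 fell (3 and 0 adjusted over the list alone). Their median of -0.07, mean of 0.51 and upward test differed in sign, and the granulocyte receptor gene Csf3r rose by 1.11 (SE 0.19, 1.09 within set B) while S100a8 stood at 1.66 without passing (limma adjusted p = 0.0657). Counts of rises and falls were 0 and 2 of 12 oligodendrocyte and myelin genes, 0 and 0 of 9 oligodendrocyte precursor markers, 2 and 1 of 14 endothelial and blood-brain barrier genes, 0 and 1 of 4 erythroid and blood genes, 2 and 1 of 10 choroid plexus markers, 0 and 0 of 9 hypothalamus and pituitary markers, 1 and 0 of 8 thalamus markers and 0 and 0 of 6 cerebellum markers. Adjusted over the list alone, these counts differed only for the thalamus (0 and 0). In the same order, the medians were -0.20, 0.06, 0.20, -0.24, 0.00, -0.10, -0.12 and 0.01, and within set B -0.07, 0.04, 0.03, 0.57, -0.02, 0.02, -0.03 and -0.04.

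Of 18 erythropoietin receptor signalling genes 2 rose and 2 fell, also adjusted over the list alone (median 0.07, 0.20 within set B), with the transcriptional regulator gene Id1 at 0.62 (SE 0.13, 0.53 within set B) and Socs3 the risers named here. These counts were near the share of calls over all tested genes. Epor, the receptor gene, was at -0.57 (SE 0.20, limma adjusted p = 0.046, -0.44 within set B). That call was lost without any 1 of VEH-Sham 1, 3 and 4, VEH-HI 6 to 10 and EPO-HI 13 (adjusted p 0.0529 to 0.143), and its adjusted p ranged from 0.0329 to 0.199 over all settings that ignore the array set. Epo itself was not analysed here, because no probe set carried its symbol alone.

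The comparison of EPO-HI with VEH-HI asks what erythropoietin before the injury changes, and all 10 of its arrays lie in set B. No probe set passed with limma (0 of 27022, smallest adjusted p = 0.138). At an unadjusted p under 0.05 there were 1066, against 1351 by chance. The count was also 0 under each of the 9 other planned settings and with the array set as a block, which changes the error estimate but not the differences and where 1377 had an unadjusted p under 0.05. Leaving out VEH-HI 8 gave 4 calls, named after their values were seen: Rgs7bp (0.91), 1435583_at and 1441550_at (both unnamed here, 0.84 and 0.75) and Nat8f4 (-1.38).

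The genes with the smallest p, none passing, were higher in EPO-HI for Nexn, an actin-binding gene (0.75, SE 0.16, limma adjusted p = 0.656), the chromatin remodelling gene Atrx (0.55, SE 0.13, 0.722), the striatal gene Ppp1r1b (0.53, SE 0.13, 0.733), the zinc finger gene Zfp729b (0.57, SE 0.14, 0.876) and Mfap3l (0.39, SE 0.10, 0.951). In the other direction stood Nbl1, a secreted antagonist of bone morphogenetic proteins (-0.98, SE 0.22, limma adjusted p = 0.656), the splicing cofactor gene Son (-0.36, SE 0.09, 0.683), the small heat shock protein gene Cryab (-0.44, SE 0.11, 0.779), the galactosyltransferase gene B4galt7 (-0.74, SE 0.19, 0.876) and the forkhead gene Foxl2 (-0.52, SE 0.13, 0.876). Epor was at 0.19 (SE 0.20).

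Although no single gene passed, camera called 7 of the 28 lists. Meningeal and fibroblast markers were lower in EPO-HI (median -0.29, camera adjusted p = 9.02e-07, below 0 in 10 of 11 members), with Col3a1 at -0.34 (SE 0.11) and the proteoglycan gene Lum at -0.36 (SE 0.14). Striatal projection neuron markers were higher (0.20, camera adjusted p = 6.03e-06, above 0 in 11 of 12), with Ppp1r1b at 0.53 and the opioid precursor gene Penk at 0.27 (SE 0.10). Sterol synthesis genes were higher (0.17, camera adjusted p = 9.02e-07, above 0 in 14 of 16), with Sc5d at 0.37 (SE 0.12) and Nsdhl at 0.32 (SE 0.11). With an estimated correlation these 3 lists had adjusted p = 0.225, 0.251 and 0.563. Exact permutation gave the meningeal list p = 0.00794, the smallest possible with 5 against 5, and the striatal list p = 0.0317, adjusted to 0.222 and 0.444.

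Microglia and macrophage markers (median -0.12, camera adjusted p = 0.000516, below 0 in 22 of 22), reactive astrocyte genes (-0.21, camera adjusted p = 0.00183) and cytokines (-0.17, camera adjusted p = 0.0257) were lower, and neuron markers were higher (0.06, camera adjusted p = 0.00277). With an estimated correlation their adjusted p = 0.563, 0.678, 0.740 and 0.563. Named members were Cd68 (-0.42, SE 0.16), the Fc receptor gene Fcgr3 (-0.42, SE 0.19), the chemokine gene Cxcl1 (-0.41, SE 0.22), Gad2, a synthase of the transmitter GABA (0.34, SE 0.14), and the kinase gene Camk2a (0.39, SE 0.16), none passing alone. All 4 calls were lost without VEH-HI 6 (adjusted p 0.225 for microglia, 0.625 for reactive astrocytes, 0.774 for cytokines and 0.284 for neurons, with medians of -0.05, -0.07, -0.04 and -0.00). Without EPO-HI 13 the first 3 were lost (0.116, 0.116 and 0.406, medians -0.07, -0.13 and -0.08), and without EPO-HI 12 the reactive astrocyte (0.0534, median -0.17) and cytokine lists (0.336, median -0.10). The cytokine list was also lost without VEH-HI 8 (0.401) and without EPO-HI 14 (0.151), with smaller medians of -0.10 and -0.11, and with the upper 40% of probe sets (0.0611), where its median was larger at -0.25. The number of called lists was 3 without VEH-HI 6, 4 without EPO-HI 13 and 11 without VEH-HI 10. A block for the array set cannot move these medians, since all 10 arrays lie in set B, and with an estimated correlation beside it 0 of the 7 were called (adjusted p 0.13 to 0.749). Fry and exact permutation called 0 of 28 after adjustment (2 at an unadjusted permutation p under 0.05).

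Adjusted over the list alone, 4 genes had a call in EPO-HI: Ppp1r1b (adjusted p = 0.00488), Hspa4l at 0.32 (0.0466) and Cryab (0.0104) among heat shock genes, and the myelin gene Mal at -0.70 (0.0441), all by limma. No member of the 28 lists passed over all tested probe sets. For 5 lists that did not pass (hypoxia, interferon, hypothalamus, cerebellum and oligodendrocyte precursors) the median, mean and test differed in sign. Erythropoietin receptor signalling genes had a median of -0.08 (camera adjusted p = 0.316), with the kinase gene Pim1 at -0.59 (SE 0.26).

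**Figure D3:**
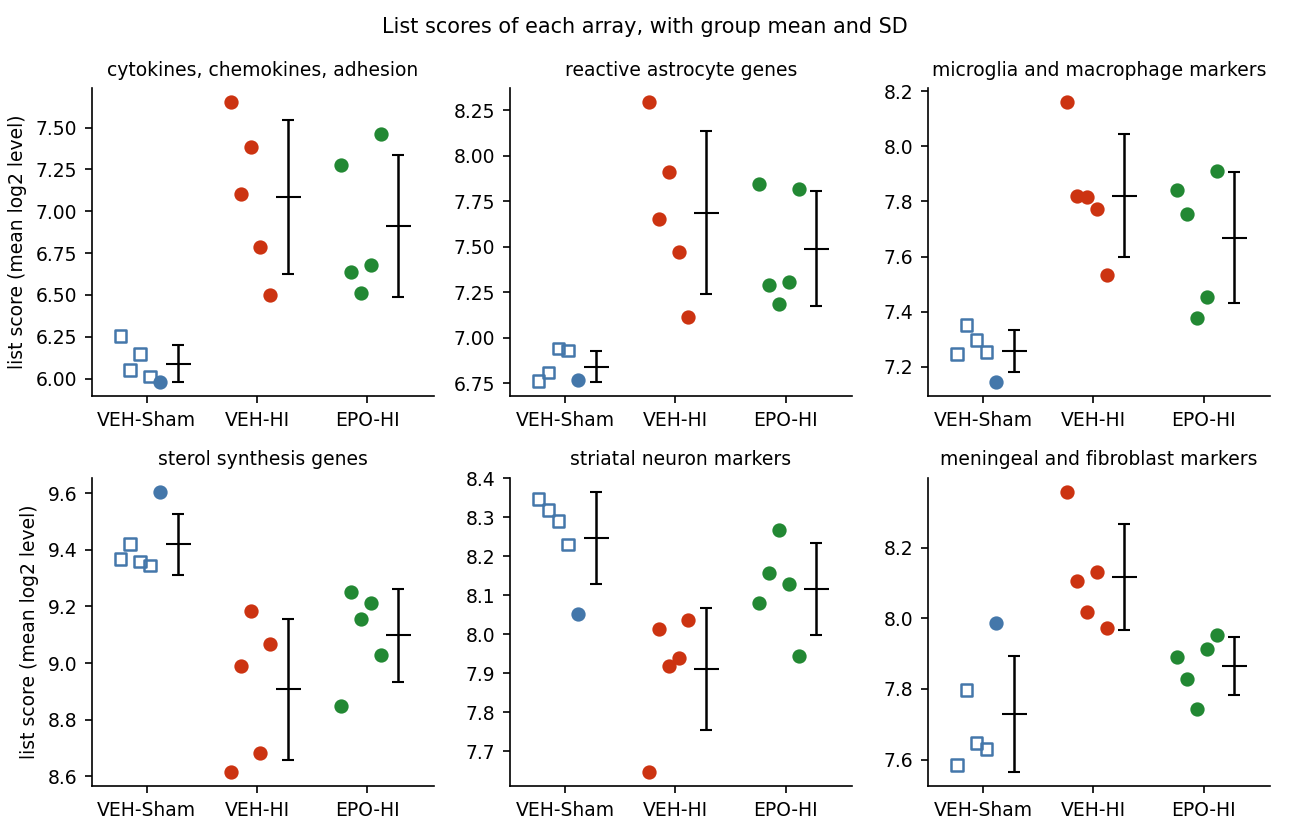
Mean log2 level of the members of 6 gene lists in each array (vertical axes), with the group mean and SD as a horizontal and a vertical bar (n = 5 per group). Open squares are arrays of set A and filled circles of set B. VEH-Sham 5 lies below all VEH-HI arrays for reactive astrocyte genes (6.77 against 7.11 to 8.30) and above them for sterol synthesis genes (9.60 against 8.62 to 9.19), while VEH-HI 6 lies at the extreme of its group in all 6 panels.

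Whether the changes after hypoxic ischemia were smaller with erythropoietin was also compared across probe sets, which are not independent replicates. The effects VEH-HI minus VEH-Sham and EPO-HI minus VEH-HI correlated at -0.31 (covariance -0.0195), but both contain the VEH-HI arrays, and simulated unchanged groups gave -0.50 (covariance -0.0137, a difference of -0.0058). With the VEH-HI arrays split so that each part served 1 effect, the mean was -0.06 (-0.17 to 0.01, below 0 in 19 of 20 splits). Within set B it was -0.42, where simulated unchanged groups gave -0.29, and -0.11 when split (below 0 in 19 of 20 splits).

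Across the 10 hypoxic ischemia arrays, the mean score of the reactive astrocyte, microglial and cytokine lists and the striatal marker score were compared, a relation examined after the data were seen. Pooled, Pearson r was -0.82 (permutation p = 0.00304) and Spearman rho -0.78 (permutation p = 0.0104), with r = -0.56 without the 2 arrays farthest from the median. With the group means taken out, r was -0.87 (permutation p = 0.00035) and rho -0.87 (permutation p = 0.00194), with r = -0.74 without the 2 farthest. For this family of 2 relations the Benjamini-Hochberg values of the Pearson tests were 0.00304 and 0.0007. All 10 arrays lie in set B.

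The comparison of EPO-HI with VEH-Sham changes injury and treatment together. Ccl12 rose by 3.58 (SE 0.38, limma adjusted p = 5.83e-05), Lgals3 by 2.21 (SE 0.28, 0.000185), Serpina3n by 2.13 (SE 0.39, 0.00288), the interferon-inducible Ifi202b by 2.12 (SE 0.42, 0.00396) and Clec16a by 2.08 (SE 0.34, 0.00165). With the array set as a block these were 3.64, 1.58, 0.95, 1.84 and 0.04. The falls were -2.03 for Ighg3, -1.93 for Bpifb1, -1.79 for Bcas2, -1.79 for Marchf10 and -1.61 for Cphx3, against -0.35, -0.70, -0.05, -0.92 and -1.03 with the block. The other probe set of Bcas2 did not share its direction in VEH-HI.

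In total 4939 probe sets passed with limma, 2005 higher (40.6%) and 2934 lower, for 1167 and 1246 genes. With the array set as a block 4 passed, named after their values were seen: 1449254_at (3.90), 1422447_at (1.64) and 1442622_at (1.54), all unnamed here, and Mnt (1.54). Within set B 5 passed, which were 1449254_at, 1442622_at, Mnt, Col27a1 (1.81) and Tm2d2 (1.15). Without VEH-Sham 1, 2, 3 and 4 the count was 2826, 3084, 2691 and 2509, without EPO-HI 11 it was 3202, and without VEH-Sham 5 it was 9047. Quantile normalization called 4104 (53.4% higher) and equal medians 8603 (88.7% higher), with the median change moved from -0.05 to 0.22.

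Camera called 9 lists in this comparison. Reactive astrocyte genes rose (12 of 21 higher and 0 lower, 12 and 2 adjusted over the list alone, median 0.93, 0.92 with the block, camera adjusted p = 3.78e-05), as did cytokines (10 of 20 higher and 1 lower, 12 and 2, median 0.64, 0.70 with the block, 4.14e-05) and microglia and macrophage markers (6 of 22 higher and 1 lower, 10 and 1, median 0.35, 0.58 with the block, 0.000112). Sterol synthesis genes fell (6 of 16 lower and 0 higher, 9 and 0, median -0.36, -0.55 with the block, camera adjusted p = 0.000221). These 4 and the neuron markers were the 5 lists called with the block, and with the block and an estimated correlation 0 were (adjusted p 0.26 for the 4 and 0.535 for neuron markers). The neuron markers turned in sign, with a median of 0.03 over all arrays and -0.09 with the block. NRF2 targets (median 0.20, camera adjusted p = 0.00936), astrocyte markers (0.16, 0.0096), interferon genes (0.23, 0.0222), cell cycle genes (0.21, 0.0321) and oligodendrocyte genes (-0.38, 0.0471) passed without the block only, at 0.08, 0.03, 0.27, 0.13 and -0.11 with it. All 9 had adjusted p = 0.646 with an estimated correlation, fry called 1 list and exact permutation 9 (adjusted p 0.037 to 0.0494), of which 8 were among these 9, the ninth being apoptosis genes. Testing only the upper 40% of probe sets also ended these 5 calls (camera adjusted p 0.0761, 0.0605, 0.0649, 0.119 and 0.0761, medians 0.20, 0.16, 0.28, 0.21 and -0.22), and 4 lists passed. The astrocyte call was lost with quantile normalization (0.114, median 0.13). The interferon and cell cycle calls were lost with equal medians (0.143 and 0.0795), although their medians grew to 0.50 and 0.49 along with that of all probe sets, and with array weights (0.0856 and 0.0685), at medians of 0.28 and 0.21. The oligodendrocyte call was lost with quantile normalization (0.0721, median -0.27), a pseudocount of 64 (0.0516, median -0.29), and, at medians of -0.38, with only the 2 groups compared (0.0506), eBayes without trend (0.0522) and array weights (0.117). The interferon call was lost without VEH-Sham 5 (0.0551), EPO-HI 11 (0.107) or EPO-HI 15 (0.0834), at medians of 0.31, 0.24 and 0.16. The cell cycle call was lost without VEH-Sham 1 (0.0605), VEH-Sham 5 (0.0551), EPO-HI 11 (0.124) or EPO-HI 15 (0.0511), at medians of 0.21, 0.21, 0.15 and 0.25. The oligodendrocyte call was lost without VEH-Sham 1 (0.0628), 2 (0.0727) or 5 (0.0805), or EPO-HI 11 (0.144), 12 (0.0577) or 13 (0.129), at medians of -0.42 to -0.32.

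Both comparisons with VEH-Sham called 1658 probe sets higher (82.7% of the higher calls of EPO-HI) and 2050 lower (69.9%), and 0 in opposite directions. All 5 VEH-Sham arrays stand in both comparisons, which raises this overlap. Their effects correlated at 0.90 across probe sets (covariance 0.128), and simulated unchanged groups that share the VEH-Sham arrays gave 0.50 (covariance 0.0158, a difference of 0.112). With the VEH-Sham arrays split between the comparisons the mean was 0.70 (0.61 to 0.76). Arrays of set A stand on both sides of each such split, so these splits leave the shared array set in place. The simulated groups hold no array-set difference, so the excess over them includes it.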

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

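The tests of the list scores against VEH-Sham 5, of the splits that keep VEH-Sham 1 to 4 together, of less specific probe sets, of the scaling, of VEH-HI 6, of the axis between injury and striatal scores, of differences between animals and of Xist were chosen only after the result was seen.

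The calls between VEH-HI and VEH-Sham followed the array set. Of 100 free splits of the 10 arrays only the real 1 gave as many (6174, highest other 6042). The 5 others that kept VEH-Sham 1 to 4 together gave 3830 to 6042 and the rest at most 1. The free splits thus follow the array set and cannot judge chance. Given the array set the real split was 1 of 6, too few for a share under 0.05. The array set as the whole cause stays open for each list compared, because the values within set B rest on 1 sham array. In unchanged groups 1 array lies below all 5 others with a chance of 16.7%, and likewise above, so no gap here can exclude it. VEH-Sham 5 lay 0.418 below the nearest VEH-HI array in the mean score of the reactive astrocyte, microglial and cytokine lists. There the SD was 0.0282 in VEH-Sham 1 to 4 and 0.372 in VEH-HI. For NRF2 targets VEH-Sham 5 lay 0.128 below (SD 0.0754 and 0.144), but its 8.70 also stood above the VEH-Sham 1 to 4 mean of 8.46. For the sterol list it lay 0.419 above (SD 0.0329 and 0.248) and stood apart from VEH-Sham 1 to 4 too. For the astrocyte and meningeal lists it lay inside the VEH-HI range, as the array set predicts (lowest VEH-HI array minus VEH-Sham 5 -0.107 and -0.0142). For the calls as a body the array set stays open as the whole cause. The slope of VEH-HI minus VEH-Sham 5 on EPO-HI minus VEH-Sham 1 to 4 was 0.0790 over 9539 calls. That lay inside the -0.0537 to 0.0815 that VEH-HI arrays gave in the place of VEH-Sham 5. The slope also lay under 0.5, the mark set in advance for the array set as a partial cause, as that cause predicts. It rests on 1 sham array. Less specific probe sets (IDs ending in _x_at, at 1.83 times their share among higher calls, over the mark of 1.5 for a part in them, and 1.23 times among lower calls) and the scaling of arrays (a share of 0.711 of the calls also made after quantile normalization, 4388 probe sets) stay open as contributors, as does hypoxic ischemia itself.

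The list shifts between EPO-HI and VEH-HI ran opposite to those called after hypoxic ischemia, with the injury lists lower and the striatal and sterol lists higher. The neuron list, higher here, had no called shift after hypoxic ischemia over all arrays (median -0.09, camera adjusted p = 0.366). Against VEH-Sham 5 alone its median was -0.19, and that of the striatal list was -0.18. The shifts between EPO-HI and VEH-HI were called by camera at its preset correlation only. An estimated correlation called 0 of the 7 (adjusted p 0.225 to 0.740), and fry and exact permutation 0 of 28. VEH-HI 6 may decide the injury and neuron part, since without it 3 of the 7 lists (meningeal, sterol and striatal) stayed called at that preset. An axis of injury that varies between samples in both groups may link the lists, but this stays open. Injury and striatal scores correlated at -0.87 with the group means taken out, a pair picked after the data were seen. Differences between samples without any part of erythropoietin also stay open, as the injury score gave an exact permutation p = 0.452 (two-sided, -0.17, and -0.05 with p = 0.802 without VEH-HI 6). Sign reversal from the shared VEH-HI arrays stays open too, as 19 of 20 splits of these arrays kept the correlation of effects below 0 but with a mean of -0.06, and erythropoietin remains an open biological explanation.

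Xist, which is transcribed from the inactive X chromosome of females, and the Y-linked genes Eif2s3y, Kdm5d and Uty were both seen on most arrays. A uniform cross-hybridisation of the Y-linked probe sets is argued against by the range of Eif2s3y within set B, 2.07 on the log2 scale (intensities of 102 to 481). RNA of males and females combined in most samples may account for the pattern, but this stays open: over the 11 arrays of set B, Xist and the mean of the 3 Y-linked genes had Pearson r = -0.80 (permutation p = 0.00215) and Spearman rho = -0.61 (permutation p = 0.0522), and without the 2 farthest arrays r was -0.28, so the relation rests on those. On VEH-HI 6 the Xist level was 4.13 (intensity 1.49) against 8.89 to 9.65 on the other VEH-HI arrays, and on EPO-HI 12 it was 7.33 against 9.05 to 9.48. No group of the design gives a biological explanation, and none was tested.

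For EPO-HI against VEH-HI, the real count was 0 (highest other 97, with calls in 6 splits), so 100 of 100 splits gave at least as many by construction and this count says nothing on chance. For EPO-HI against VEH-Sham, 2 of 100 splits gave as many as the real 4939 (highest other 5707). The 5 other splits that kept VEH-Sham 1 to 4 together gave 3585 to 5707 and the rest at most 1. These free splits also follow the array set and cannot judge chance. Among the 6 splits that kept those arrays together, 2 gave as many, the real one included, and 6 are too few for a share under 0.05.

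An array stood far from the rest of its group in 18 of 135 groups of 5 tested, where chance gives about 1 in 20 for independent groups. These groups were not independent, since they share arrays, many genes were chosen as calls against VEH-Sham, and array medians also defined the sets. Of the lists, only those called in VEH-HI against VEH-Sham or EPO-HI against VEH-HI were tested. The untested hypothalamus and pituitary list stood at 8.85 in EPO-HI 15 (others 7.64 to 7.74) and 8.64 in VEH-Sham 3 (others 7.76 to 7.87). VEH-Sham 5 stood apart in its median (5.80, others 6.16 to 6.21), its score on the first principal component (13.2, others -56.9 to -49.7), the sterol synthesis list (9.60, others 9.34 to 9.42) and Clec16a (7.23, others 4.47 to 4.88). It was also apart for Bcas2 (8.59, others 10.51 to 10.95), Bpifb1 (5.62, others 6.96 to 7.34), Casz1 (5.62, others 7.19 to 7.60), Igdcc3 (5.47, others 7.37 to 7.87) and Ighg3 (5.34, others 7.25 to 7.65). VEH-HI 6 stood apart in the neuron list (9.61, others 9.76 to 9.82), Ccl3 (8.33, others 6.96 to 7.09) and Tmem266 (4.90, others 4.70 to 4.76), besides Xist. EPO-HI 11 was apart in the neuron list (9.70, others 9.85 to 9.91) and Marchf10 (4.54, others 5.48 to 5.80), VEH-HI 8 in Marchf10 (4.53, others 5.68 to 5.95) and EPO-HI 15 in Ppp1r1b (7.54, others 7.83 to 7.90).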

How the results depend on the processing

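The array set as a block, the mixed set alone, the block with quantile normalization and the exact permutation of list scores were chosen after seeing the data, and the cause of each change below was not tested unless stated. Among named genes of VEH-HI against VEH-Sham, the array-set settings kept 0 of 231 values of called genes past the threshold, 214 in the same direction and 17 reversed; by construction these fits rest on 1 sham array. Leaving out 1 array of the 2 groups compared kept 702 of 770 past it and ended 68 calls, and the other settings kept 648 of 677 and ended 29. S100a8, which did not pass with all arrays, passed in 2 of 15 values without 1 array, 2 of 9 under other settings and 0 of 3 under the array-set settings. Reversed with the block, in the mixed set alone and with block and quantile normalization were Clec16a (-0.061, -0.061 and -0.077), Bcas2 (0.17, 0.17 and 0.18), Tac1 (0.17, 0.17 and 0.20) and Ldha (-0.061, -0.061 and -0.078). Igdcc3 (0.012 and 0.012) and Igf2 (-0.010 and -0.010) reversed in the first 2 of these, and Pecam1 in the last (-0.026). The counts of called probe sets under these 3 settings were 3, 7 and 2 for VEH-HI (the 2 being 1442622_at, unnamed here, and Mnt, seen after the fact) and 4, 5 and 2 (the same 2) for EPO-HI against VEH-Sham. For EPO-HI against VEH-HI they were 0 each. Leaving out 1 array gave 3824 to 9609 for VEH-HI against VEH-Sham (VEH-Sham 4 and 5), 0 to 4 for EPO-HI against VEH-HI (4 without VEH-HI 8) and 2509 to 9047 for EPO-HI against VEH-Sham (VEH-Sham 4 and 5). The other planned settings gave 4261 to 8611, 0 and 3008 to 9212; for EPO-HI against VEH-Sham the upper 40% gave 3008 (fewer probe sets tested), equal medians 8603 and array weights 9212. Called lists numbered 8 to 13 without 1 array for VEH-HI against VEH-Sham (13 without VEH-HI 10), 3 to 11 for EPO-HI against VEH-HI (VEH-HI 6 and 10; 4 without EPO-HI 13) and 6 to 10 for EPO-HI against VEH-Sham (6 without VEH-Sham 5 or EPO-HI 11). With no filter 14 lists passed for VEH-HI, and 5 with the block, of which 4 were among the 8 (0 with the block and an estimated correlation, in each comparison with VEH-Sham). For EPO-HI against VEH-Sham 4 passed with the upper 40%, 5 with the block, 4 with block and quantile normalization and 1 with fry. An estimated correlation gave 0, 0 and 0 lists, and for EPO-HI against VEH-HI fry gave 0 and exact permutation 0. At the preset correlation of camera, the 8 list calls of VEH-HI held in 80 of 80 values without 1 array of the 2 groups and in 72 of 72 under 9 settings of scaling, filter and model, and 11 of 24 were lost under the array-set settings. For EPO-HI against VEH-HI 11 of 70 were lost without 1 array and 1 of 63 under those 9 settings; for EPO-HI against VEH-Sham these were 13 of 90 and 15 of 81, and 15 of 27 under the array-set settings. An estimated correlation kept 0 of 8, 0 of 7 and 0 of 9, and fry 8, 0 and 1. The named genes of EPO-HI against VEH-Sham passed in 100 of 100 values without 1 array and 85 of 85 under other settings, and in 0 of 30 under the array-set settings, and none of EPO-HI against VEH-HI passed in any. The correlation of the effects of hypoxic ischemia and erythropoietin lay between -0.37 (without VEH-HI 8) and -0.24 (without EPO-HI 13), and was -0.38 for the upper 40%, -0.057 with VEH-HI split, -0.51 over called probe sets, which were selected with the same VEH-HI arrays, and -0.42 in the mixed set. Signal over background limits dim genes, whose changes the added constant of 16 understates.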

Other observations

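Levels in all 3 groups were compared, only after the result was seen, for the 10 genes named in EPO-HI against VEH-HI (the 5 with the smallest p in each direction), none of which passed (limma adjusted p 0.656 to 0.951). In 8 of them (not B4galt7 and Foxl2) the VEH-HI mean lay above or below both other group means, and 4 of the 8 are given here. Nexn was at 6.88 ± 0.15 in VEH-Sham, 5.93 ± 0.41 in VEH-HI and 6.68 ± 0.13 in EPO-HI (SD, n = 5 each), and Atrx at 10.18 ± 0.13, 9.48 ± 0.37 and 10.03 ± 0.12. Ppp1r1b stood at 7.92 ± 0.30, 7.27 ± 0.11 and 7.80 ± 0.14, and Son at 9.17 ± 0.13, 9.99 ± 0.11 and 9.63 ± 0.09. Of the other probe sets, 3 of 6 for Son and 5 of 6 for Atrx shared the direction of VEH-HI minus VEH-Sham. From VEH-Sham 5 alone, VEH-HI differed by -0.72 for Nexn, -0.78 for Atrx, -0.30 for Ppp1r1b and 0.62 for Son. All 10 were chosen for a small p against VEH-HI, and the same VEH-HI arrays stand in both differences, which favours an extreme VEH-HI mean.

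The signal of added control RNA, taken after the scaling of each array, differed between several arrays as well. It does not show whether the amounts added differed. Hybridisation spikes averaged 9.81 to 9.89 on the log2 scale in set A and 9.16 to 9.81 in set B, and polyadenylated spikes 7.36 to 7.46 and 7.32 to 8.44.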
